A study of Petunia x hybrida with 12 samples.

How the data were processed

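Petal RNA from 4 groups of Petunia x hybrida was measured on 12 one-colour oligonucleotide arrays, 3 per group. The groups were the untransformed line W115 and W115 carrying a 35S-driven grape transgene, VvMYB5a, VvMYB5b or VvMYBA1. Per the labels' protocols, total RNA was extracted with Trizol, amplified to antisense RNA and labelled with an Alexa Fluor dye. Each group was taken from the transgene label, and the replicate number from the sample title.

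The deposited scanner tables hold, per the file headers, the median intensity of each probe on a linear scale, together with how many copies of the probe were used or left out. Each array listed 27748 probes, of which 27594 had petunia contig identifiers and 154 were controls. No background column and no gene name came with the probes. The scanner software and the authors' normalization are not given in the sources used here. The deposited series value table holds intensity values of the same 12 arrays. Set against the scanner medians, each of its columns was the scanner column times 1 factor, from 0.841 to 1.12, with a largest relative deviation of 5.0e-08 percent. Each factor equalled the array's own median over all probes divided by 552.1. Arrays had thus been multiplied by their medians, and the table medians ranged from 390.8 to 691.8, against 464.5 to 618.0 for the scanner medians. The table is on a linear scale, is not centred by probe and has no reference sample, so that none of scale, centring and direction stayed unknown. It was used only as an alternative.

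The scanner medians were background corrected by normexp with an offset of 50, fitted on all probes of each array. Petunia probes were then put on the log2 scale and quantile normalized. A probe with no copy used on an array was treated as missing there. This concerned 62 probes of VvMYB5a replicate 1, on which 12252 copies of 9985 probes had been left out; no copy was left out on the other arrays. One linear model with the 4 group means was fitted per probe to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with no covariate. Changes were called at a Benjamini-Hochberg adjusted p under 0.05 over the probes tested, and calls with a fitted change of at least 2-fold were counted beside them. All adjusted p-values are two-sided and from limma. Standard errors (SE) are those of the fit; means and standard deviations (SD) are of the normalized log2 intensities of 3 arrays.

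A probe was taken as above background on an array when its scanner median exceeded the 95th percentile of the 77 negative-control probes of that array. This level ranged from 526.0 to 961.8 intensity units, and 35.6% to 47.4% of petunia probes exceeded it. Where a probe was not above this level on any array of a group and was above it on all 3 arrays of the other, the fold is given as a lower bound. The bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal above the level and the probe's own. The number of arrays limits the precision.

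The fit and the calling were tested on simulated normalized arrays with the real probe means and spreads. In these, 200 of 27594 probes were changed in a single line. The noise was independent between arrays and held no slide effect. Background correction and quantile normalization were not part of this test. For the VvMYB5a comparison with wild type, 41% of probes changed by 1 log2 unit and 93% of those changed by 2 were recovered. For VvMYB5b the shares were 52% and 93%, and for VvMYBA1 47% and 95%. The share of false calls was 4.29%, 8.23% and 4.05%.

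Slides were inferred from a number in the names of the deposited scanner data, and arrays with the same number were taken to share a slide. What the number marks was not checked otherwise. Slide 1 held wild-type replicate 2, VvMYB5b replicates 1 and 2 and VvMYBA1 replicates 1 and 2. Slide 2 held wild-type replicates 1 and 3 and replicate 3 of VvMYB5b and of VvMYBA1. The 3 VvMYB5a arrays lay on 3 further slides with no other sample. Slide was therefore used as a fixed block for the 9 arrays on the shared slides, and as a random block, with an estimated correlation of 0.19, for all 12 arrays.

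The samples, the design, the rule for named probes and most alternatives were fixed before the data were examined. The rule took, per comparison with wild type, the 2 probes with the largest rise and the 2 with the largest fall among those that passed the test and whose 3 line arrays all lay on one side of the 3 wild-type arrays. It would have named more genes, by lists of the flavonoid pathway, vacuolar acidification, scent, other petal functions and other tissues, had the probes carried gene names. The files do not pair probe identifiers with gene names, so none of these lists was tested and the planned camera tests were not run. Genome positions and gene annotations of the probes were not analysed here, and neither were levels of the grape transgenes.

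Overlaps of calls between lines were set against 100 simulated sets of 12 unchanged arrays that shared the wild type, and against independent lists of the same sizes. The alternatives were no background correction, 75th percentile scaling, cyclic loess, a filter on dim probes, the deposited value table, only the 6 arrays compared, the replicate number as a block, slide as a block, comparison within a slide, an eBayes fit with trend and robust settings, and leaving out each array. Dividing each array by its median, removing each array's trend with probe GC content, and keeping only probes with every copy used were chosen after seeing the data.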

Results

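The petals of W115, a white-flowered petunia line, were compared at stage 5 to 6 with petals of 3 W115 lines that overexpressed a grape MYB transcription factor. VvMYB5a and VvMYB5b are grape regulators of flavonoid synthesis, and VvMYBA1 is a grape regulator of anthocyanin synthesis. The design asked how each transgene changed the petal transcriptome. Each of the 4 groups had 3 arrays, with scanner medians from 464.5 to 618.0 intensity units. Between 9120 and 11481 of 27594 petunia probes were above the negative-control level on all 3 arrays of a group. Normalized log2 intensities correlated across probes at 0.94 to 0.99 within groups and 0.90 to 0.97 between groups, and no 2 arrays shared more than 0.41% of their scanner values exactly. Nothing in the labels says that the 3 samples of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. Nor do the labels say how many independent transformants a line stands for, so changes are those of the line. Probes are named by their identifiers, since the files give no gene names.

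The VvMYB5a line had 1621 probes called against wild type, 716 higher and 905 lower, or 5.87% of those tested. The fitted change was at least 2-fold for 256 of the higher and 532 of the lower probes. The largest rise was that of PETAX006060_Contig1_540_40_S (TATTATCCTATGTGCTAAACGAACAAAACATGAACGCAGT), from 9.77 ± 0.44 in wild type to 14.37 ± 0.22 (log2, SD, n = 3 each). That change of 4.60 log2 units (SE 0.24) was 24.3-fold, with an adjusted p of 4.7e-07 in limma; 2 of the 3 wild-type arrays were above the negative-control level. PETAX089413_Contig1_294_40_S (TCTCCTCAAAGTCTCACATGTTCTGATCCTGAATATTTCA) rose from 8.03 ± 0.30, not above that level on any wild-type array, to 11.89 ± 0.30. It was at least 6.24-fold higher (adjusted p 6.6e-06). Of the probes that fell, PETAX010275_Contig2_46_40_S (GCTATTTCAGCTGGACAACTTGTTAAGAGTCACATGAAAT) went from 12.67 ± 0.63 to 9.04 ± 0.44, a fitted change of -3.62 (SE 0.31, adjusted p 1.9e-05), with 1 of the 3 VvMYB5a arrays above the negative-control level. All 4 contigs that share its PETAX number fell, by -3.62 to -2.81 log2 units. PETAX100344_Contig1_381_35_S (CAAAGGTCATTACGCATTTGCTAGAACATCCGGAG) went from 12.01 ± 0.36 to 8.43 ± 0.53, below the negative-control level on every VvMYB5a array, and was at least 6.38-fold lower (adjusted p 2.9e-04). No wild-type array was above that level at 294 of the 716 raised probes, and at 71 of these all 3 VvMYB5a arrays were. At the others of the 294, at least 1 VvMYB5a array was within background too. At 1617 of the 1621 called probes the 3 line arrays lay on one side of the 3 wild-type arrays. A call with 3 arrays against 3 nearly requires this, so it is no further support. Over all probes 26.3% were so separated, where chance gives 10%. Probes of an array can move together, so this share can depart from 10% without an effect of the line.

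VvMYB5a lay on slides of its own, and slide as a random block left 1066 calls. The share of higher calls, 44.2%, was 33.6% with 75th percentile scaling, 32.7% with arrays divided by their medians, 29.5% in the deposited table and 32.5% without VvMYB5a replicate 1. In the other direction, it was 50.4% without VvMYB5a replicate 3 and 49.8% with the replicate number as a block. The count was 810 with arrays divided by their medians, 616 in the deposited table, 625 without wild-type replicate 1, 486 without wild-type replicate 3, 536 without VvMYB5a replicate 1 and 520 without VvMYB5a replicate 2. It rose to 2016 without wild-type replicate 2 and to 2001 without VvMYB5a replicate 3. With the replicate number as a block it was 2755, although these numbers were not taken as pairs. The filter on dim probes tested 12255 probes and called 1709, of which 1202 were among the 1621 and in the same direction. With every copy used, 17755 probes were tested and 1162 called, of which 1088 were among the 1621. A probe not tested could not be called. Of the 1621 calls, cyclic loess kept 1443, 75th percentile scaling 1134, no background correction 1572 and trend and robust eBayes 1585.

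The VvMYB5b line had 563 probes called, 223 higher and 340 lower than wild type, or 2.04% of those tested, and 441 of them had a fitted change of at least 2-fold. PETAX006060_Contig1_540_40_S again rose most, to 14.89 ± 0.14, a change of 5.12 log2 units (SE 0.24, n = 3) or 34.8-fold (limma adjusted p 1.1e-07). PETAX078379_Contig1_297_40_S (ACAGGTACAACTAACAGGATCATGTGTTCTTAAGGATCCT) was above the negative-control level on every wild-type array, at 11.06 ± 0.36, and rose to 15.63 ± 0.19. Its change of 4.56 (SE 0.35) was 23.6-fold (adjusted p 8.0e-06). PETAX028934_Contig1_427_38_S (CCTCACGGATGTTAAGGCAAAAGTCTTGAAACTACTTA) fell from 13.05 ± 0.58 to 8.91 ± 2.09, a fitted change of -4.14 (SE 0.79, adjusted p 0.014). Its VvMYB5b arrays were far apart, with replicate 1 at 11.32 and replicates 2 and 3, not above the negative-control level, at 7.78 and 7.63. The adjusted p of this probe was 0.077 without wild-type replicate 1, 0.088 without VvMYB5b replicate 2 and 0.061 without VvMYB5b replicate 3, with fitted changes of -3.80, -3.57 and -3.50. This p ranged from 5.5e-13 to 0.088 over its alternatives other than comparison within a slide. The 5.5e-13 came from the deposited value table, where all named changes had an adjusted p of 2.6e-12 or less. It is therefore no sign that the VvMYB5b arrays of this probe were close together. PETAX012427_Contig1_607_37_S (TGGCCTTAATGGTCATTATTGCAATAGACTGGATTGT) fell from 11.48 ± 0.33 to 7.76 ± 1.06, below the negative-control level on all 3 VvMYB5b arrays, and was at least 4.59-fold lower (adjusted p 2.2e-04). No wild-type array was above that level at 111 of the 223 raised probes, and at 55 of these every VvMYB5b array was. The arrays of the 2 groups did not overlap at 562 of the 563 called probes, and at 12.9% of all probes, where chance gives 10%. The limits given for VvMYB5a hold for both values.

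Over the 9 arrays of the shared slides, 396 probes were called with slide as a fixed block and 438 without it. The share of higher calls, 39.6%, was 24.1% in the deposited table and 50.2% without wild-type replicate 1, and 122 of the 244 calls without VvMYB5b replicate 2 were higher. On slide 1 and slide 2 the change of PETAX006060_Contig1_540_40_S was 5.55 and 4.99, that of PETAX078379_Contig1_297_40_S 4.59 and 4.42, that of PETAX028934_Contig1_427_38_S -3.15 and -5.59 and that of PETAX012427_Contig1_607_37_S -3.23 and -4.27, values from 1 wild-type array on slide 1 and 1 VvMYB5b array on slide 2; those of the fallen probes rest on VvMYB5b signals that were mostly within background, and the 5.55 on a wild-type signal within it. Only the 6 arrays compared gave 304 calls, and leaving out single arrays gave 279 without wild-type replicate 1, 266 without wild-type replicate 3, 1060 without VvMYB5b replicate 1, 244 without VvMYB5b replicate 2 and 323 without VvMYB5b replicate 3.

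The VvMYBA1 line had the fewest called probes against wild type, 206, of which 141 were higher and 65 lower, or 0.747% of those tested. The fitted change was at least 2-fold for 125 of the higher and 48 of the lower probes. At 73 of the 141 raised probes no wild-type array was above the negative-control level, and at 53 of them every VvMYBA1 array was. PETAX087824_Contig3_164_35_X4 (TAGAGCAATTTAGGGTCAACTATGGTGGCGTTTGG) rose from 7.89 ± 0.55 to 14.37 ± 0.05 (log2, SD, n = 3 each), at least 34.8-fold (limma adjusted p 3.6e-09). Of the 5 contigs with its PETAX number, 4 rose and 1 was not called, with a lowest change of 0.17. PETAX024978_Contig2_286_40_S (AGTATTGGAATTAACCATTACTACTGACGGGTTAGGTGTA) rose from 5.94 ± 0.19 to 12.18 ± 0.23, at least 7.63-fold (adjusted p 1.7e-09), and both contigs with its PETAX number rose. PETAX041506_Contig1_636_40_S (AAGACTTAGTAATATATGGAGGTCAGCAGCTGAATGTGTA) fell from 11.03 ± 0.50 to 7.78 ± 0.46, at least 3.95-fold (adjusted p 1.7e-05). PETAX078379_Contig1_297_40_S, raised in VvMYB5b, fell from 11.06 ± 0.36 to 8.38 ± 0.94 in VvMYBA1, at least 4.03-fold (adjusted p 7.5e-04). Neither fallen probe was above the negative-control level on any VvMYBA1 array. The arrays of the 2 groups did not overlap at any of the 206 called probes, and at 18.0% of all probes, where chance gives 10%. The limits given for VvMYB5a hold here too.

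With slide as a fixed block over 9 arrays 152 probes were called, and 155 without it. On slide 1 and slide 2 the change of PETAX087824_Contig3_164_35_X4 was 7.10 and 6.19, that of PETAX024978_Contig2_286_40_S 6.27 and 6.40, that of PETAX041506_Contig1_636_40_S -3.19 and -3.03 and that of PETAX078379_Contig1_297_40_S -2.21 and -3.74, from 1 wild-type array on slide 1 and 1 VvMYBA1 array on slide 2; each sets a signal against one within background, and none is a measured fold. The share of higher calls, 68.4%, was 10.1% in the deposited table, in which the median of all probes shifted by -0.50; it was 54.3% without wild-type replicate 2 and 78.9% with slide as a fixed block. The count was 835 in the deposited table, 110 without wild-type replicate 3, 110 without VvMYBA1 replicate 1 and 369 without VvMYB5b replicate 1.

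**Figure D1:**
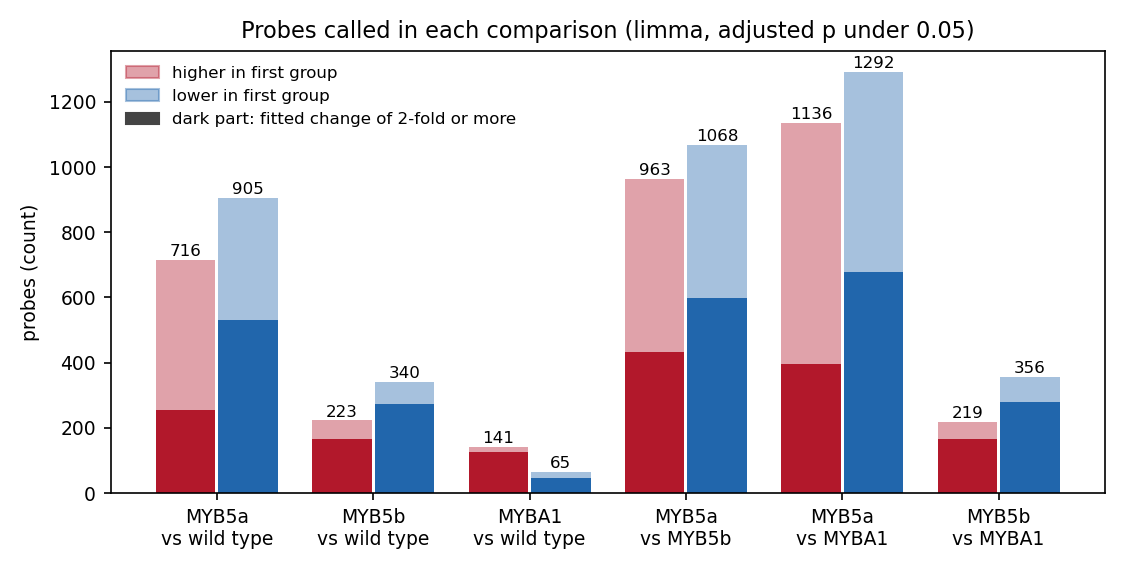
Number of probes called per comparison (vertical axis, count from 0), with probes higher in the first-named group in red and lower in blue; the dark part of each bar is the number with a fitted change of 2-fold or more. VvMYB5a had 716 higher and 905 lower probes than wild type, VvMYB5b 223 and 340, and VvMYBA1 141 and 65.

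The number of calls against wild type was highest in VvMYB5a and lowest in VvMYBA1, but large rises had the opposite order. A fitted rise of at least 8-fold was found for 4 called probes in VvMYB5a, 14 in VvMYB5b and 40 in VvMYBA1. A fitted fall of that size was found for 10, 6 and 1. Some of these fitted changes rest on a signal within background. Of the 12 fits with 1 array left out, VvMYB5a had the most calls in 11; without VvMYB5a replicate 2 it had 520, against 541 in VvMYB5b. In the deposited value table, where arrays were multiplied by their medians, VvMYBA1 had the most calls, 835, against 616 in VvMYB5a and 518 in VvMYB5b. The lines were also compared directly. VvMYB5a differed from VvMYB5b at 2031 probes, 963 higher and 1068 lower, and from VvMYBA1 at 2428 probes, 1136 higher and 1292 lower. VvMYB5b differed from VvMYBA1 at 575 probes, 219 higher and 356 lower. The share of higher calls in these comparisons was 47.4%, 46.8% and 38.1%. It was 62.3%, 94.4% and 68.2% in the deposited table, and 37.4% in the first with arrays divided by their medians. Single arrays also turned it. For VvMYB5a against VvMYB5b it was 56.1% without VvMYB5a replicate 2 and 51.0% without VvMYB5b replicate 3. For VvMYB5a against VvMYBA1 it was 52.4% without VvMYB5a replicate 3. Relative to wild type and to both other lines, 245 probes were higher and 338 lower in VvMYB5a, 63 higher and 77 lower in VvMYB5b, and 75 higher and 16 lower in VvMYBA1.

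PETAX006060_Contig1_540_40_S was at 8.46 ± 0.37 in VvMYBA1, not above the negative-control level, and was at least 40.02-fold higher in VvMYB5a and at least 57.2-fold higher in VvMYB5b (limma adjusted p 3.0e-09 and 2.8e-09). Its difference between VvMYB5a and VvMYB5b, -0.52 (SE 0.24), was not called (adjusted p 0.22). PETAX078379_Contig1_297_40_S was at 13.96 ± 0.10 in VvMYB5a, 7.46-fold above wild type (adjusted p 4.1e-04), and at least 95.3-fold higher in VvMYB5b than in VvMYBA1 (adjusted p 1.4e-08). PETAX087824_Contig3_164_35_X4 also rose in VvMYB5b, to 10.51 ± 0.40 and at least 2.40-fold above wild type (adjusted p 8.2e-05), and its difference between VvMYB5b and VvMYBA1 was -3.86 (SE 0.27, adjusted p 9.4e-07). In VvMYB5a it stood at 8.78 ± 0.30 and was not called against wild type (adjusted p 0.063). PETAX024978_Contig2_286_40_S was not above the negative-control level in wild type, VvMYB5a or VvMYB5b.

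Without single arrays the count for VvMYB5a against VvMYB5b was 974 and 1074 (without VvMYB5a replicates 1 and 2) and 3145, 1035 and 771 (without VvMYB5b replicates 1, 2 and 3), and 1093 from the 6 arrays alone. For VvMYB5a against VvMYBA1 it was 918, 775 and 4146 (without VvMYB5a replicates 1, 2 and 3) and 1246, 922 and 1265 (without VvMYBA1 replicates 1, 2 and 3). For VvMYB5b against VvMYBA1 it was 360 and 336 (without VvMYB5b replicates 2 and 3), 375 and 372 (without VvMYBA1 replicates 1 and 2), and 593 with slide as a fixed block. With slide as a random block the counts were 1715, 2217 and 772, and each comparison with VvMYB5a also sets its slides against others.

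**Figure D2:**
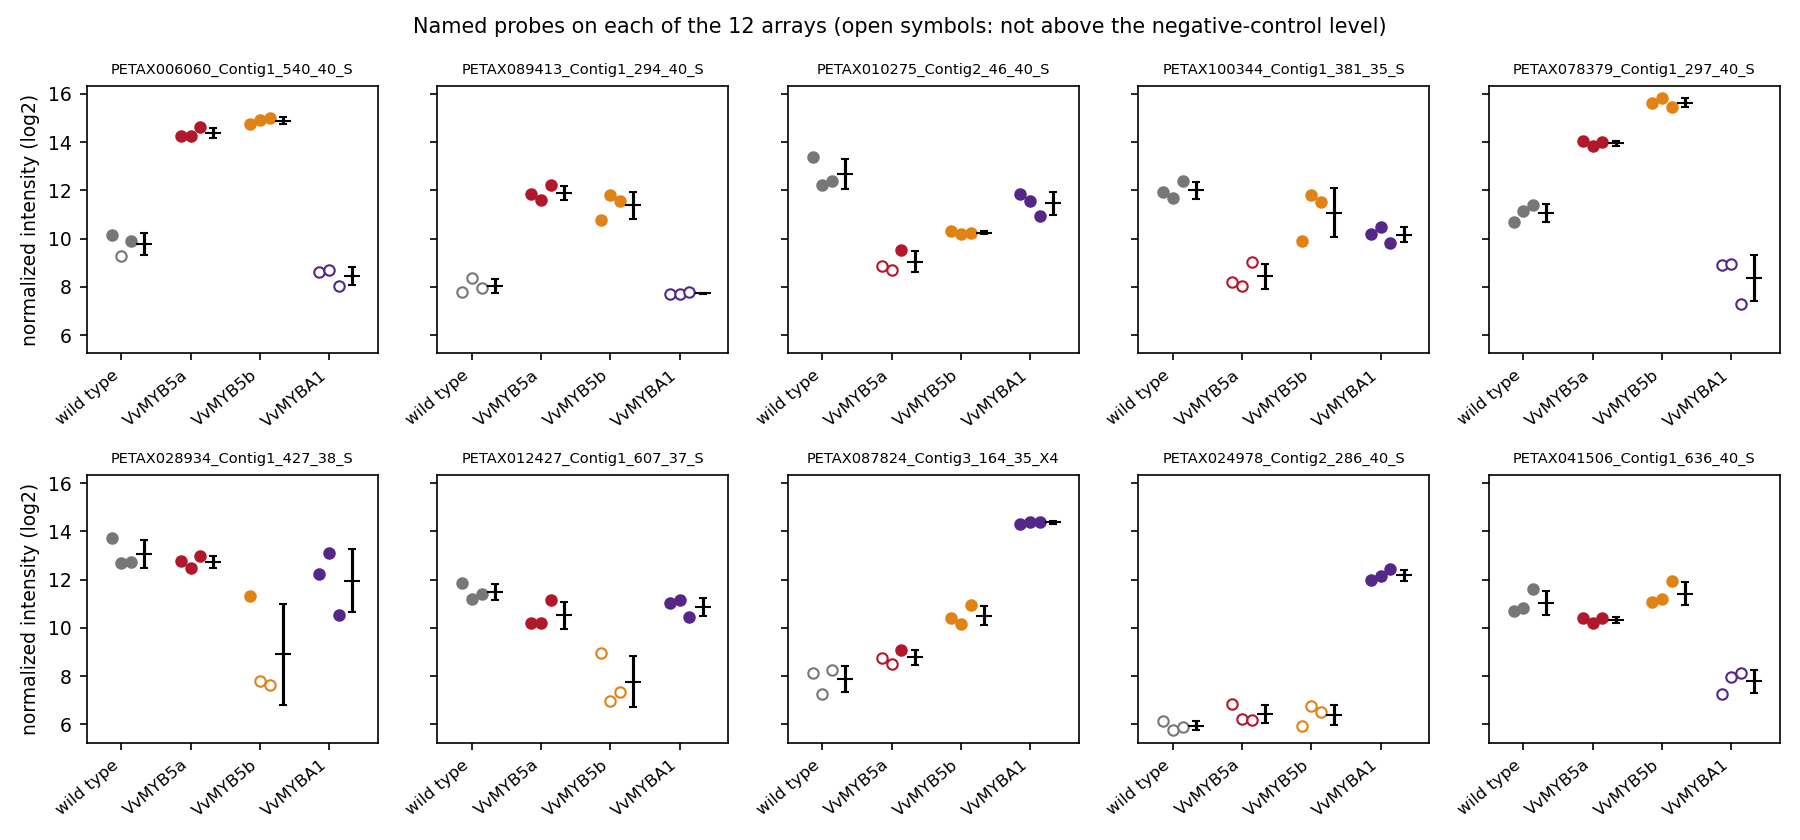
Normalized intensity (log2, vertical axis) of the 10 named probes on each array, by group; filled symbols were above the negative-control level of their array and open symbols were not, and bars are the mean and SD of 3 arrays. PETAX006060_Contig1_540_40_S stands above 14 on all VvMYB5a and VvMYB5b arrays, and PETAX024978_Contig2_286_40_S is above the negative-control level on VvMYBA1 arrays alone.

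Calls were shared between lines. VvMYB5a and VvMYB5b shared 68 raised and 88 lowered probes, VvMYB5a and VvMYBA1 shared 30 and 27, and VvMYB5b and VvMYBA1 shared 46 and 25. Independent lists of these sizes would share 5.79 and 11.2, 3.66 and 2.13, and 1.14 and 0.80 probes. Simulated unchanged lines that shared the wild-type arrays had on average 0.00, 0.02 and 0.00 calls in common, but only 0.14 or 0.15 calls each, so this does not measure what the shared arrays add to the overlap. Probes called in opposite directions numbered 20, 11 and 9, where independent lists would give 16.1, 6.31 and 2.26. All 3 lines shared 18 raised and 16 lowered probes. Of the 2107 probes called in any line, 1865 were called in 1 line, 201 in 2 and 41 in 3.

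Across probes, which are not independent replicates, fitted changes correlated at 0.37 between VvMYB5a and VvMYB5b, 0.23 between VvMYB5a and VvMYBA1 and 0.44 between VvMYB5b and VvMYBA1, each below the 0.50 of simulated unchanged lines that shared the wild-type arrays. Their covariances were 0.064, 0.041 and 0.061, against 0.028 for each pair in simulated unchanged lines, a difference of 0.036, 0.013 and 0.034. The wild type could not be split into 2 parts of at least 2 arrays, so part of the overlap may come from the shared wild-type arrays. Changes were therefore also taken against a wild-type array kept out of the selection of probes (replicates 1, 2 and 3 in turn). Probes raised in VvMYB5a then had a median change of 0.019, -0.081 and 0.22 log2 units in VvMYB5b and -0.028, -0.20 and -0.11 in VvMYBA1, and probes lowered in it -0.25, -0.0011 and -0.39, and -0.36, 0.023 and -0.39. Against the central 95% of 10000 random probe sets matched on mean intensity, only 1 of these 6 medians at raised probes, the 0.22, lay above, and -0.081, -0.20 and -0.11 lay below; at lowered probes 4 of the 6 lay below, and 0.023, against wild-type replicate 2, lay above. Probes raised in VvMYB5b had 0.51, 0.40 and 0.75 in VvMYB5a and 0.18, 0.16 and 0.25 in VvMYBA1, and probes lowered in it -0.75, -0.10 and -0.55, and -0.67, -0.11 and -0.40. Probes raised in VvMYBA1 had 0.18, 0.45 and 0.34 in VvMYB5a and 0.27, 0.39 and 0.30 in VvMYB5b, and probes lowered in it -0.47, -0.021 and -1.03, and -0.20, -0.31 and -0.51. Of these 24 medians 23 lay beyond the random sets in the direction of the selection, and the -0.021 did not. The random sets were drawn probe by probe and do not carry deviations that probes share on an array. Lying beyond them is therefore no measure of the spread between arrays. Wild-type replicates 1 and 3 both lay on slide 2, so with either kept out the other stayed in the selection. With replicate 2 kept out, the medians at lowered probes were smaller in size, except in VvMYB5b at probes lowered in VvMYBA1. The lists of lowered probes were then also longer than with replicate 1 or 3 kept out. They held 1108 probes against 370 and 306 in VvMYB5a, 329 against 139 and 148 in VvMYB5b, and 79 against 34 and 24 in VvMYBA1. Shared falls may partly reflect the wild-type arrays of slide 2, but a longer list may also give smaller medians. Shared calls in one direction numbered 81, 30 and 43 without wild-type replicate 1 and 86, 25 and 35 without wild-type replicate 3, against 156, 57 and 71 with all arrays. In the deposited table they numbered 118, 160 and 185. For VvMYB5a and VvMYB5b they were 86 without VvMYB5a replicate 1, 101 without VvMYB5a replicate 2 and 99 without VvMYB5b replicate 2, for VvMYB5a and VvMYBA1 31 without VvMYB5a replicate 1, 33 without VvMYBA1 replicate 1 and 97 without VvMYB5b replicate 1, and for VvMYB5b and VvMYBA1 163 without VvMYB5b replicate 1 and 38 without VvMYBA1 replicate 1.

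**Figure D3:**
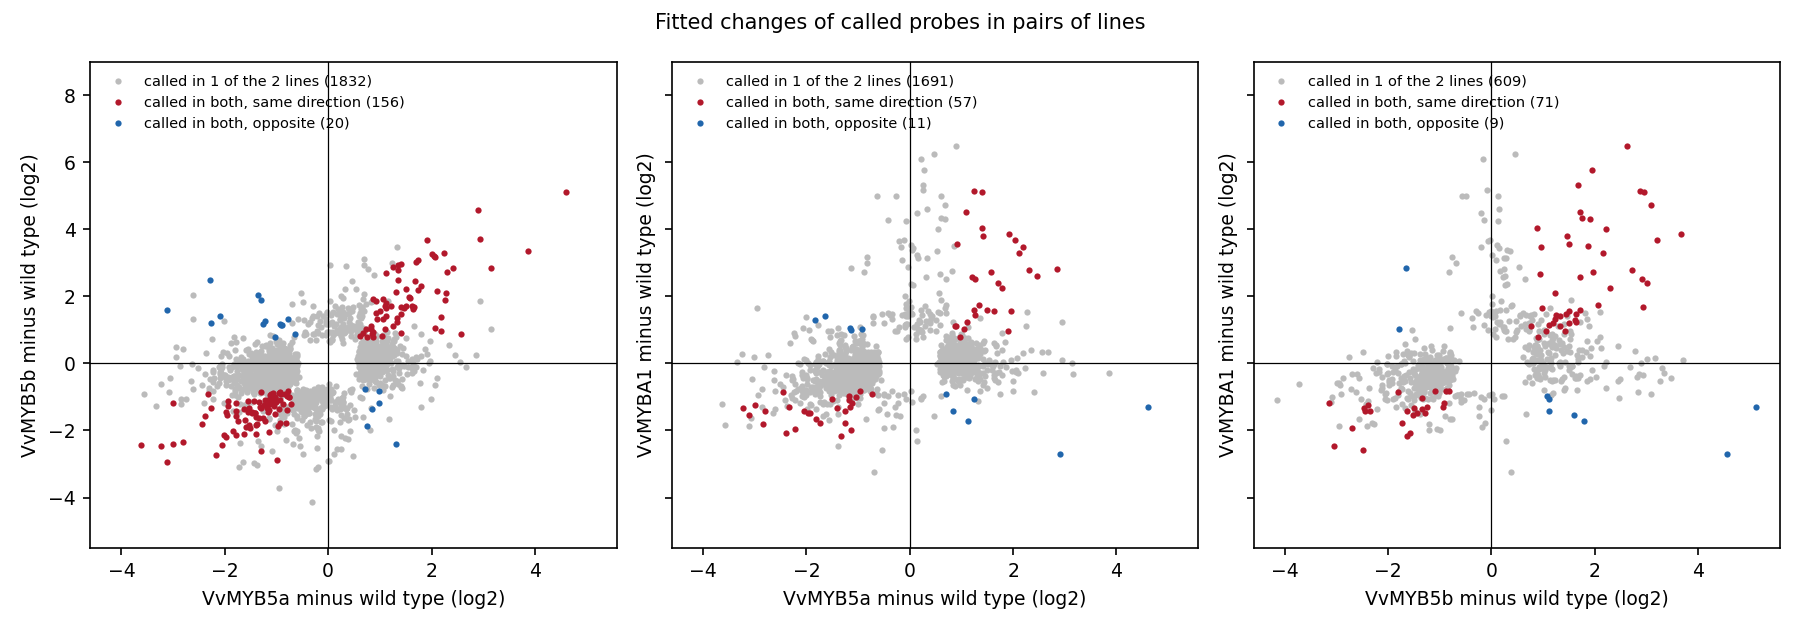
Fitted change against wild type (log2) of called probes in each pair of lines, one line per axis; red points were called in both lines in the same direction, blue points in opposite directions and grey points in 1 line of the pair. The red points number 156, 57 and 71 from left to right, and the blue points 20, 11 and 9.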

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

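The test of admixture and the test of a wrong label were chosen after the results they bear on were seen. The results below were picked out because the change against wild type differed between 2 lines by the direct test of the difference (limma, adjusted p under 0.05). Signed values are the first-named line minus the second, in log2 units. Where one line was below the negative-control level, the fitted difference rests on a signal within background.

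The change differed between VvMYB5a and VvMYB5b at 2031 probes, between VvMYB5a and VvMYBA1 at 2428 and between VvMYB5b and VvMYBA1 at 575. VvMYB5a minus VvMYB5b was -1.20 for PETAX010275_Contig2_46_40_S, -2.65 for PETAX100344_Contig1_381_35_S, -1.66 for PETAX078379_Contig1_297_40_S, 3.83 for PETAX028934_Contig1_427_38_S, 2.76 for PETAX012427_Contig1_607_37_S, -1.73 for PETAX087824_Contig3_164_35_X4 and -1.07 for PETAX041506_Contig1_636_40_S. VvMYB5a minus VvMYBA1 was 5.92 for PETAX006060_Contig1_540_40_S, 4.15 for PETAX089413_Contig1_294_40_S, -2.42 for PETAX010275_Contig2_46_40_S, -1.73 for PETAX100344_Contig1_381_35_S, 5.59 for PETAX078379_Contig1_297_40_S, -5.59 for PETAX087824_Contig3_164_35_X4, -5.76 for PETAX024978_Contig2_286_40_S and 2.56 for PETAX041506_Contig1_636_40_S. VvMYB5b minus VvMYBA1 was 6.44 for PETAX006060_Contig1_540_40_S, 3.64 for PETAX089413_Contig1_294_40_S, 7.25 for PETAX078379_Contig1_297_40_S, -3.12 for PETAX012427_Contig1_607_37_S, -3.86 for PETAX087824_Contig3_164_35_X4, -5.78 for PETAX024978_Contig2_286_40_S and 3.63 for PETAX041506_Contig1_636_40_S.

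VvMYB5a had more called probes than the other lines, and its arrays lay on slides of their own. The GC content of the probes is argued against as the whole cause, since 89.7% of the called probes were still called with the GC trend removed, as are the spots left out of replicate 1, since the call rate among probes with every copy used was 1.04 times that over all probes. For the 1621 probes slide and line cannot be told apart, because no other group shared those slides. The 2 shared slides differed at 0 probes in limma with group in the model, at an adjusted p under 0.05. At an unadjusted p under 0.05 they differed at 5637 of 27594 probes, a larger share than the 0.05 that no difference would give. The 0 calls are therefore no sign that slide differences were absent. An effect of VvMYB5a itself stays open and untested.

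VvMYB5b replicate 1 stood apart from replicates 2 and 3, and leaving it out raised the count against wild type from 563 to 1060. At the probes then called, its change was a median 0.36 of that of the other replicates for the 452 risen probes and 0.46 for the 608 fallen ones. The fraction lay between 0.93 and 1.09 when replicates 2 and 3 were placed in the same way. Those fractions rest on fewer probes, 122 to 191 per direction, called with replicate 1 in the fit. The sets of probes are therefore not alike. An array of another group under a wrong label is argued against: at probes that set replicates 2 and 3 apart from all other groups, its median position was 0.25 (bootstrap 95% interval 0.21 to 0.32) between the nearest other group at 0 and these replicates at 1, and none of the 9 arrays of other groups had a median above -0.056. Admixture of wild-type RNA stays open: its signal would need a wild-type share of 40.7% (37.8 to 44.6) at fallen and 73.9% (66.2 to 78.4) at risen probes, but among probes changed at least 4-fold the shares were 27.6% (19.2 to 35.9) and 39.9% (29.6 to 54.9), whose intervals overlap. A difference between plants of the line was not tested.

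For splits of the 6 arrays of a comparison into 3 and 3, of which there are 10, a share under 0.05 cannot be reached; 1 of the 10, the real one, gave as many probes in each of the 6 comparisons. The real count and the highest of the other splits were 1621 and 561 for VvMYB5a against wild type, 563 and 1 for VvMYB5b against wild type, and 206 and 2 for VvMYBA1 against wild type. They were 2031 and 0 for VvMYB5a against VvMYB5b, 2428 and 0 for VvMYB5a against VvMYBA1, and 575 and 37 for VvMYB5b against VvMYBA1. The split with 561 calls exchanged VvMYB5a replicate 3 and wild-type replicate 2. Its sides also differed in the negative-control level. This level was 779.0, 961.8 and 862.25 intensity units on VvMYB5a replicates 1 and 2 and wild-type replicate 2. On VvMYB5a replicate 3 and wild-type replicates 1 and 3 it was 648.9, 652.9 and 671.2. Whether such a background difference between arrays adds to the 1621 calls was not tested.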

How the results depend on the processing

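Dividing arrays by their medians, removing the GC trend and keeping only probes with every copy used were chosen after seeing the data. No named change reversed in any setting run. Outside the comparisons within a slide, 11 of the 12 named changes against wild type stayed past the threshold in all of their settings. PETAX028934_Contig1_427_38_S missed it without 3 single arrays (changes of -3.80 to -3.50, limma adjusted p 0.061 to 0.088). Its lowest adjusted p over these settings, 5.5e-13, was that in the deposited value table. Within slide 1 that probe and PETAX012427_Contig1_607_37_S missed it, with changes of -3.15 and -3.23 from 1 wild-type array. The latter and PETAX078379_Contig1_297_40_S had copies left out and no value in the last added setting.

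Leaving out 1 array of the groups compared gave 486 to 2016 calls for VvMYB5a against wild type, 244 to 1060 for VvMYB5b, 110 to 173 for VvMYBA1, 771 to 3145 for VvMYB5a against VvMYB5b, 775 to 4146 for VvMYB5a against VvMYBA1 and 336 to 822 for VvMYB5b against VvMYBA1. Shared calls, without 1 array of the wild type or of the 2 lines, were 81 to 202 for VvMYB5a and VvMYB5b, 25 to 58 for VvMYB5a and VvMYBA1 and 35 to 163 for VvMYB5b and VvMYBA1. Without VvMYB5b replicate 1, VvMYBA1 had 369 calls and shared 97 with VvMYB5a. Other settings moved counts over 1.5 times. The deposited value table gave 616 calls for VvMYB5a and 835 for VvMYBA1 against wild type, 1126 for VvMYB5a against VvMYB5b, 5651 for VvMYB5a against VvMYBA1, and 160 and 185 calls shared by VvMYBA1 with VvMYB5a and VvMYB5b. Its scaling shifted the median of all probes by -0.21 in VvMYB5b and -0.50 in VvMYBA1 against wild type, and by 0.20, 0.46 and 0.27 between the lines (VvMYB5a against VvMYB5b and VvMYBA1, then VvMYB5b against VvMYBA1). Dividing by the medians gave 810 for VvMYB5a against wild type and 1347 against VvMYBA1. Only the 6 arrays compared gave 304 for VvMYB5b against wild type and 1093 for VvMYB5a against VvMYB5b. Slide as a random block gave 1066 for VvMYB5a against wild type, a comparison that then carries the spread between slides. In the same fit the counts on the shared slides rose by less than 1.5 times. They were 689 for VvMYB5b and 288 for VvMYBA1 against wild type, and 772 between these lines. Within slide 1 the counts were 12 for VvMYB5b and 52 for VvMYBA1 against wild type and 126 between them, and within slide 2 they were 1052 and 792 against wild type. At least 1 group had a lone array there, assumed to vary like the other groups, and the spread had 2 and 1 residual degrees of freedom, so these fits say nothing about stability; of the VvMYBA1 calls 49 were higher and 3 lower within slide 1, and 359 and 433 within slide 2.

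Some scalings moved the share of higher calls by more than 10 percentage points. In the deposited table it went from 44.2% to 29.5% for VvMYB5a, from 39.6% to 24.1% for VvMYB5b and from 68.4% to 10.1% for VvMYBA1 against wild type. No background correction, 75th percentile scaling and cyclic loess kept all 9 counts within 1.5 times. So did the dim-probe filter, trend and robust eBayes, both other added settings and, for its 3 counts, a fixed slide block. None kept every call.

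With the replicate number as a block, 2755 probes were called for VvMYB5a against wild type, and the other 8 counts stayed within 1.5 times. Deviations of same-numbered arrays from their group means correlated at -0.33 to 0.53, above 0.1 in 7 of 18 pairs, and 6 of 12 arrays correlated best with an array of their own number, so the numbers were not taken as pairs. The planned tests of gene lists were not run under any setting. Signal over background limits the dim probes, since at most 47.4% of petunia probes exceeded the negative-control level on an array.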

Other observations

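Contigs whose identifiers share a PETAX number moved together. Among 3407 such numbers with at least 2 contigs, the changes of the first and second contig correlated across numbers at 0.33 in VvMYB5a, 0.56 in VvMYB5b and 0.52 in VvMYBA1, against -0.033 to 0.036 for the central 95% of 1000 shuffles in any of the 3 comparisons with wild type. At least 2 contigs were called for 85 PETAX numbers in VvMYB5a, 44 in VvMYB5b and 20 in VvMYBA1. Their called contigs all went one way for 83, 44 and 20 of these. In VvMYB5a 17 such numbers rose and 66 fell, in VvMYB5b 17 rose and 27 fell, and in VvMYBA1 19 rose and 1 fell.

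At the probes raised in VvMYBA1, VvMYB5b tended to move the same way. VvMYB5b shared 46 of these 141 probes as raised. With the wild-type array of the change kept out of the selection, the median VvMYB5b change was 0.27, 0.39 and 0.30 log2 units for the 3 wild-type arrays. These lay above the central 95% of 10000 random probe sets matched on mean intensity (upper ends 0.11, 0.062 and 0.14). The random sets were drawn probe by probe, so lying above them does not exclude deviations that such probes share on an array. That the median was positive against each of the 3 wild-type arrays argues against noise of 1 of them as the whole cause. It cannot exclude a deviation common to all 3, since they may not come from separate plants. With slide as a fixed term the median was 1.08 times that without it, which argues against the shared slides. A response of petal genes to both grape regulators may account for the pattern, as a hypothesis found and tested on the same data. The change of VvMYB5a at such probes, with medians of 0.18, 0.45 and 0.34, leaves an effect of transformation itself open. That effect was not tested, since no group was transformed without a grape transgene.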
